A study of Homo sapiens with 4 samples.

How the data were processed

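Single cells of the RPE1-hTERT line, an immortalised human retinal pigment epithelial line, carried the FUCCI reporters, whose CDT1 and Geminin fluorescence tells cell cycle phases apart. Per the labels' protocols, cells received 200 ng/mL neocarzinostatin (NCS), a drug that breaks both strands of DNA, 24 h or 48 h before harvest, or DMSO vehicle 24 h before harvest. Per the series' design text, wild-type cells and cells with CRISPR/Cas9 deletion of E2F7 and E2F8 (the knockout cells) were mixed before capture, and the lipophilic dye DiD on either genotype told them apart under the microscope. Per the labels' protocols, libraries were made with an automated form of CEL-Seq2, which counts tags at the 3′ end of transcripts, and were sequenced as paired ends. Per the submitters' processing notes, BWA 0.6.2-r126, STAR and Seurat 3 were used. Those notes name the hg38 (GRCh38) genome for 3 plates and hg19 (GRCh37) for the plate of vehicle replicate 3. Which tool did which step, the filters on cells, the handling of molecular identifiers and the strand used in counting are not given in the sources used here.

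The deposited expression table held natural log values, made by the authors as the log of 1 plus counts per 10000. Back-transformed values summed to 10000 in every cell. The smallest steps gave whole counts for 100% of the values above 0 within a tolerance of 0.001, and both the total count and the number of genes recovered this way equalled the deposited per-cell counts in 180 of 180 cells. The deposited per-cell table also held the percent of counts from mitochondrial transcripts and from spike-in transcripts, and the fluorescence intensity of CDT1, Geminin and DiD in arbitrary units as the authors measured it. Phase and genotype of each cell were the authors' deposited labels, and their thresholds are not given in the sources used here. Of 12235 genes in the table, 20 carried names turned into dates, held 0.135% of the counts and were left out.

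Cells are not replicates, so values were averaged per unit, the cells of a single plate, treatment and genotype. The 4 GEO samples, taken as plates, gave 5 combinations of plate and treatment and 10 units. Vehicle replicate 1 and the 24 h cells are different wells of one GEO sample, and vehicle replicate 2, vehicle replicate 3 and the 48 h cells are a GEO sample each. The run codes in the cell names give vehicle replicate 1 and the 24 h cells different dates, and vehicle replicates 2 and 3 the same date and different wells, so that the shared plate of the former rests on the GEO sample and the latter may not be independent. By the deposited DiD signal, wild-type cells carried the dye in vehicle replicate 1 and at 24 h, and knockout cells in the other 3 combinations. Counts per cell ran from 4073 to 293640 with a median of 56616.5, so levels under about 0.1 per 10000 rest on few counts in the smaller units. The main quantity was log2(mean counts per 10000 + 0.25), and all fold changes are on that scale, which understates changes of low genes. Of 11088 genes detected in at least 10% of cells, the 11060 seen in plates of both genome builds were tested.

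Tests used limma 3.58.1 with a mean-dependent prior in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. Genotypes were compared with the combination as a block. NCS was compared with vehicle within each genotype with the plate as a random block (duplicateCorrelation, statmod 1.5.0, consensus correlation 0.170). Each NCS arm is a lone unit per genotype and was assumed to vary like the vehicle units. The change of the genotype difference with NCS was tested on the knockout minus wild-type difference of each combination. Of 22 gene lists written before the data were examined, 20 had at least 5 tested members and were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over lists within a comparison. Camera and fry cannot use the random block, so lists at 24 h were tested with the plate as a fixed factor. This sets the 24 h cells of a genotype against both genotypes of vehicle replicate 1, adjusted for the mean genotype difference of the 3 vehicle plates. The medians and gene counts given beside these 24 h tests come from the limma fit against all 3 vehicle plates, which is another contrast. Lists at 48 h and over both times were tested without a block. The list of replication-dependent histones kept 4 tested members and the list of markers of other cell types 2, and neither was tested. Phase shares carry exact Clopper-Pearson 95% intervals, which like all counting intervals here cover counting error only. A share of 0 allows up to 3 cells of the unit's total. Shares and fluorescence were compared between genotypes by exact sign-flip permutation over pairs. Nothing in the labels says that plates came from separate cultures, so p-values measure only the spread between these plates, which may be technical.

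The pairing of genotypes comes from the design, since both were captured together. In a check, deviations of the genotypes from their group means correlated at 0.303, 0.232 and 0.0453 within vehicle plates, against 0.0127 at most between plates. Scripts were tested on simulated data made from the real means and depths with 100 genes changed at each of 2 sizes, over 11009 simulated genes. Its spread was chosen, with a natural-log SD of 0.2 between combinations and again between units, and a gamma shape of 1 between cells. The changed genes had a real mean of at least 1 per 10000. The recovered share of genes changed by 4-fold was 86% for the genotype comparison in vehicle, 98% for the genotype comparison over all treatments, 5% and 25% for 24 h in wild-type and knockout cells, 2% and 13% for 48 h, 56% and 67% for both times averaged, and 6% for the change of the genotype difference. Of genes changed by 2-fold, 7% and 14% were recovered for the genotype comparisons, 5% for each average and 0% for the others. In that simulation 5 of 30 calls for 24 h in knockout cells and 2 of 4 calls for 48 h in wild-type cells were false.

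The rule for named genes was written before the data were examined. For each comparison it named E2F7 and E2F8, the 10 genes with the largest change among those passing adjusted p 0.05 with the same sign in every pair or against every vehicle unit and a level of at least 0.5 per 10000 in the higher group, further genes of smallest p where fewer passed, and the 4 members of smallest p of each called list. The genes described are a part of those, picked after their values were seen. Some of those genes are not reported here. Alternatives written in advance were a pseudocount of 1, no detection filter, averages of the deposited log values, median-of-ratios scaling, leaving out each vehicle replicate, no replicate block, other minimum cell numbers, no requirement on genome builds, and fry or an estimated correlation for lists. Chosen after the data were seen were edgeR 4.0.16 on summed recovered counts, cells with at least 10000 counts, leaving out each gene's highest cell, Geminin-negative or G1 cells only, scaling for single NCS times, vehicle replicates 2 and 3 as 1 pair, the run date as block, 24 h lists without the plate factor, and vehicle replicate 1 alone as control at 48 h. Phase subsets kept units of at least 2 cells, which left out the 1 knockout G1 cell of vehicle replicate 3. The edgeR fits kept the combination block for genotype but had no plate block for NCS against vehicle. Gene locations are from the GENCODE annotation of GRCh38. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.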

Results

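The transcriptomes of 180 single RPE1-hTERT FUCCI cells were compared, 98 wild-type and 82 with E2F7 and E2F8 deleted (knockout). E2F7 and E2F8 are atypical E2F transcription factors known to repress E2F target genes, and the comparisons ask how their loss and DNA breakage by neocarzinostatin (NCS) alter expression. There were 95 vehicle cells on 3 plates, 55 cells at 24 h of NCS and 30 cells at 48 h. Total counts per unit of plate, treatment and genotype ran from 290151 (10 wild-type cells, vehicle replicate 2) to 2418596 (31 wild-type cells, vehicle replicate 1), and the whole table held 11753675. The median mitochondrial percent was 8.96 to 12.4 in the units of vehicle replicates 2 and 3 and 15.2 to 19 in the others. Levels are mean counts per 10000, given for vehicle as mean (SD) of 3 units. NCS arms had 1 unit per genotype and so no SD.

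E2F7 (chromosome 12, 77021247 to 77065580 in GRCh38) stood at 0.828 (SD 0.468, n = 3) in wild-type and 0.245 (SD 0.0406, n = 3) in knockout vehicle cells. The log2 difference was -1.01 ± 0.27 (SE) and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.119). E2F8 (chromosome 11, 19224063 to 19241620) was near the detection floor, at 0.0234 in wild-type and 0.0198 in knockout vehicle cells. A deletion made by CRISPR need not remove the 3′ tag, so these levels do not check the genotype labels. By pair, the E2F7 difference was -0.07, -1.37 and -1.58 in vehicle, -0.53 at 24 h and 0.59 at 48 h, so that E2F7 was about equal in vehicle replicate 1 and higher in knockout cells at 48 h. Without vehicle replicate 1 the vehicle difference was -1.47 (limma adjusted p = 0.00462), and with averages of the deposited log values it was -0.41 (limma adjusted p = 0.0486).

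FUCCI phases differed widely between plates. Cells called M/early G1, with low CDT1 and low Geminin signal, made up 3.23%, 10% and 0% of wild-type vehicle cells on the 3 plates (0 of 10 cells allows up to 30%), and 0%, 57.9% and 76.9% of knockout vehicle cells (0 of 12 allows up to 25%). After 24 h of NCS they made up 15.2% (95% interval 5.11 to 31.9) of wild-type and 50.0% (28.2 to 71.8) of knockout cells. At 48 h the shares were 0% of 14 wild-type and 50.0% (24.7 to 75.3) of 16 knockout cells. Wild-type G1 calls went from 36.3% (SD 21, n = 3) in vehicle to 72.7% (54.5 to 86.7) at 24 h and 92.9% (66.1 to 99.8) at 48 h, while knockout G1 calls were 16.9% (SD 9.31, n = 3), 18.2% (5.19 to 40.3) and 43.8% (19.8 to 70.1). Mid S/G2 calls made up 41.9%, 0% and 0% of wild-type vehicle cells on the 3 plates (0 of 10 cells allows up to 30%). In knockout vehicle cells they made up 50.0%, 15.8% and 7.69%. No mid S/G2 call was made among 33 wild-type cells at 24 h, which allows a share of up to 9.09%, against 31.8% (13.9 to 54.9) of 22 knockout cells. A wild-type share of 0% beside a higher knockout share was thus also seen without NCS. Over the 5 pairs, the knockout minus wild-type difference was 41.3 percentage points for M/early G1 (SD 29.2, higher in 4 of 5, exact permutation p = 0.125, adjusted p = 0.219), -32.4 for G1 (SD 19.9, lower in 5 of 5, exact permutation p = 0.063, adjusted p = 0.146) and 13.9 for mid S/G2 (SD 10.7, higher in 5 of 5, exact permutation p = 0.063, adjusted p = 0.146). The log10 median CDT1 signal was lower in knockout cells in 5 of 5 pairs, by a mean of -1.46 (SD 0.70, exact permutation p = 0.063, adjusted p = 0.146). With 5 pairs no two-sided p below 0.063 is possible, and 7 measures were tested. Shares are of cells captured and kept, and the phase mix stands beside every difference in cell cycle genes that follows.

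**Figure D1:**
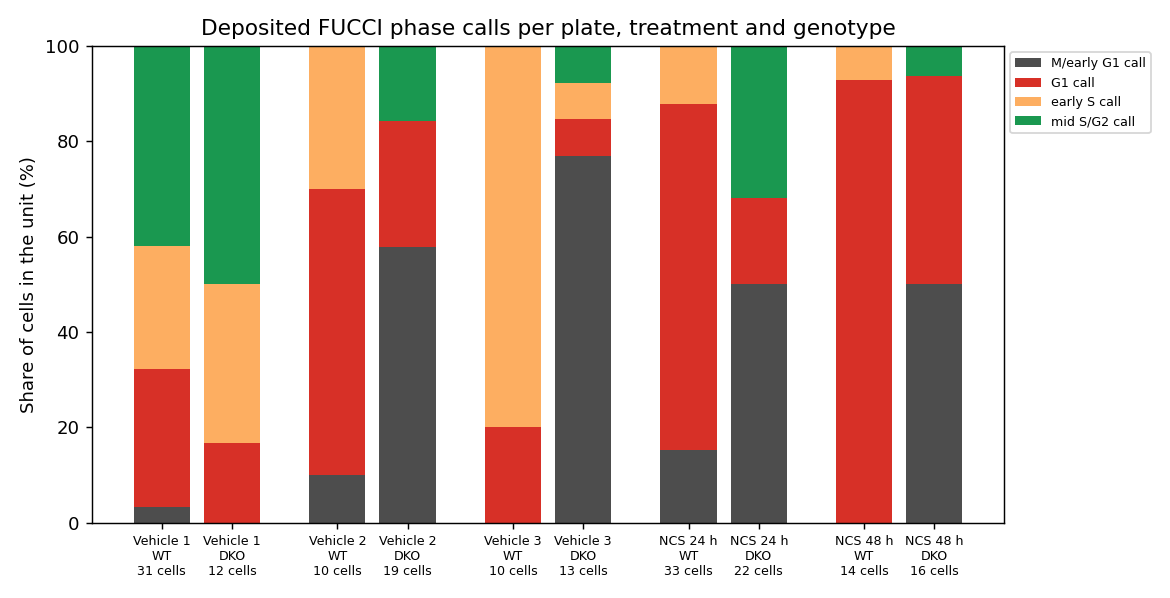
Stacked bars give the percent of cells (vertical axis) with each deposited FUCCI phase call in each of the 10 units, with the cell number under each bar. M/early G1 calls make up 50.0% of knockout cells at 24 h and at 48 h, against 15.2% and 0% of wild-type cells.

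In vehicle, 3 of the 70 G1/S E2F targets were higher in knockout cells, while the list as a whole did not pass. MCM5 (chromosome 22, 35400063 to 35425430), a subunit of the replicative helicase, was at 1.10 (SD 0.507, n = 3) in wild-type and 2.85 (SD 1.03, n = 3) in knockout cells, a log2 difference of 1.23 ± 0.20 (SE). MCM6 (chromosome 2, 135839626 to 135876426), of the same complex, was higher by 1.11 ± 0.22, and DUT (chromosome 15, 48331011 to 48343373), which removes dUTP, by 1.01 ± 0.17. The adjusted p was 0.00102, 0.00601 and 0.00102 (limma, Benjamini-Hochberg). PEG10 was higher by 1.06 ± 0.24. The histone gene HIST1H4C (-1.18 ± 0.21), asparagine synthetase ASNS (-1.34 ± 0.26), the collagen COL13A1 (-1.16 ± 0.25), the activin antagonist FST (-1.09 ± 0.24), the sialyltransferase ST6GAL2 (-1.25 ± 0.27) and the urokinase gene PLAU (-0.94 ± 0.21) were lower in knockout cells (limma adjusted p 0.00152 to 0.0227). In all, 22 of 11060 genes passed limma's test, 12 higher and 10 lower, and 9 passed after median-of-ratios scaling, 8 higher and 1 lower. Without vehicle replicate 2, 7 genes passed, and none passed without the replicate block or in G1 cells only (limma, 463 and 404 genes at unadjusted p under 0.05, edgeR 56 genes passing with the block in all cells). In Geminin-negative cells the MCM5 difference was 0.06, that of MCM6 0.88 and that of DUT 0.67, and in G1 cells that of MCM5 was -0.04. PLAU turned to 1.10 in Geminin-negative and 0.32 in G1 cells. The G1 results rest on vehicle replicates 1 and 2, with 2 and 5 knockout cells, since replicate 3 had 1 knockout G1 cell.

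**Figure D2:**
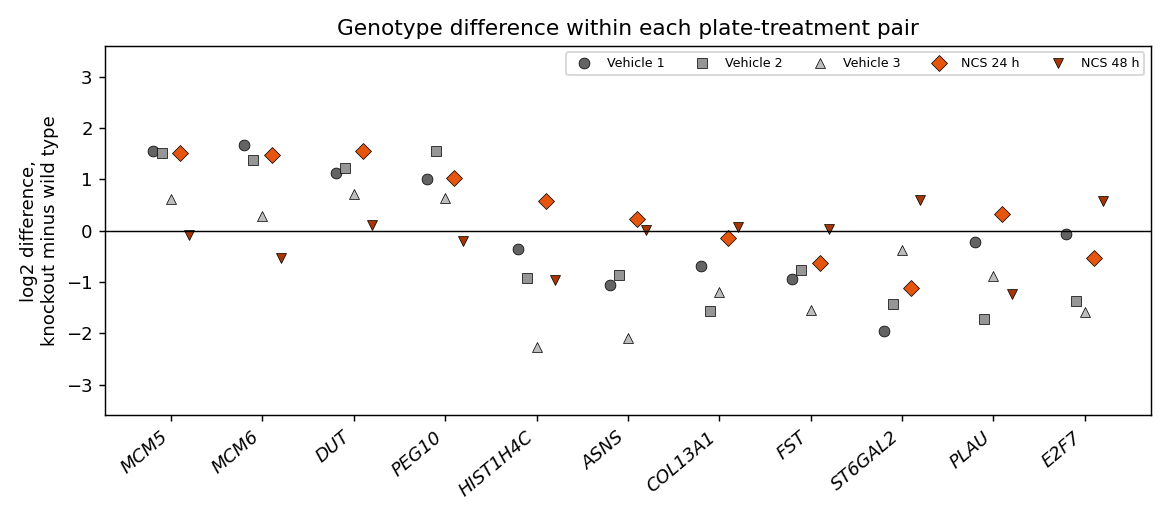
Each point is the log2 difference in counts per 10000, knockout minus wild type (vertical axis), of a gene (horizontal axis) in 1 of the 5 combinations of plate and treatment. MCM5, MCM6 and DUT lie above 0 in the 3 vehicle pairs and at 24 h, and MCM5 and MCM6 lie below 0 at 48 h.

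Of the fixed lists in vehicle, 8 passed camera with its preset correlation (adjusted p 5.3e-07 to 0.0278) and 0 passed otherwise (adjusted p = 0.649 to 0.825 with an estimated correlation). Among 25 TGF-beta and YAP targets the median log2 difference was -0.29, with 0 genes lower over all genes and 5 adjusted over the list alone. Their mean was -0.52, -0.31 and 0.08 in the 3 vehicle pairs. THBS1 (-0.65 ± 0.20) did not pass over all genes and was at 0.80 in replicate 3. Of 26 genes of the unfolded protein and amino acid response, ASNS was lower over all genes and 4 were adjusted over the list alone, where PSAT1 (-0.84 ± 0.23), a serine synthesis enzyme, and the cystine transporter SLC7A11 (-0.70 ± 0.21) had the next values. TUBA1B, an alpha tubulin, was lower by -0.51 ± 0.12 (limma adjusted p = 0.0377) among 27 cytoskeleton and keratin genes, of which 6 were lower and 2 higher adjusted over the list alone. MT-ND1, of respiratory complex I, was higher by 0.43 ± 0.10 (limma adjusted p = 0.0377) among 17 mitochondrial transcripts, of which 5 were higher adjusted over the list alone. The 63 G2/M markers had a median of -0.16 (0 over all genes, 2 lower adjusted over the list alone), with SMC4 at -0.78 ± 0.19 and a mean of 0.30, -0.27 and -0.52 in the pairs. The 33 homologous recombination and crosslink repair genes had a median of -0.11 (0 in both counts) and a mean of 0.13, -0.27 and -0.41 in the pairs. Interferon-stimulated genes and cytosolic ribosomal proteins had medians of 0.19 and 0.07 (0 in both counts). Of the 8 lists, 2 (cytoskeleton and keratin genes, mitochondrial transcripts) were called without each vehicle replicate in turn. The median of cytoskeleton and keratin genes was 0.09 in G1 and -0.01 in Geminin-negative cells, and that of mitochondrial transcripts 0.15 in both. TGF-beta and YAP targets were not called without replicate 1, and G2/M markers and homologous recombination genes not without replicate 2 or 3. The 70 G1/S E2F targets did not pass camera (median -0.06, adjusted p = 0.584), although 3 were higher over all genes and 6 higher and 1 lower adjusted over the list alone. Their mean was 0.58, -0.12 and -0.45 in the pairs. The S phase markers had 0.55, -0.10 and -0.53. Both lists did pass camera without vehicle replicate 1, where the pairs left lay below 0. They also did so without replicate 3, where replicate 1 lay well above 0 and replicate 2 slightly below. These passes thus do not repeat one effect. The median of the G1/S targets was -0.46 in G1 and -0.36 in Geminin-negative cells.

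Over vehicle and NCS together, knockout cells had less PTX3, a secreted pattern recognition protein (-1.19 ± 0.18), and TGM2, a transglutaminase (-0.67 ± 0.13). They had more of the growth factor gene MDK (1.08 ± 0.20), DUT (0.94 ± 0.16), ECM1 (0.87 ± 0.17), the carboxypeptidase CPA4 (0.85 ± 0.13), the ferritin light chain FTL (0.64 ± 0.11), MT-ND1 (0.41 ± 0.08) and MCM5 (1.03 ± 0.20). These were among 11 genes that passed (limma adjusted p 0.00541 to 0.0487), 9 higher and 2 lower. LAMA4 (0.80 ± 0.17) and SEMA7A (-0.70 ± 0.15) missed (limma adjusted p 0.0804 and 0.105). Of the lists, 7 passed camera with preset correlation (adjusted p 3.97e-10 to 0.0342) and 0 with an estimated correlation (adjusted p = 0.148 to 0.824), while cytoskeleton and keratin genes also passed fry (adjusted p = 0.0191). The 17 mitochondrial transcripts had a median of 0.21 (1 higher over all genes, 7 adjusted over the list alone), and the 70 G1/S E2F targets 0.09 (2 and 5). Cytoskeleton and keratin genes had a median of -0.16 (0 over all genes, 6 lower and 1 higher adjusted over the list alone). Medians were -0.14 for TGF-beta and YAP targets, -0.16 for the amino acid response, -0.14 for ribosome biogenesis and 0.09 for interferon-stimulated genes. Without each vehicle replicate in turn, cytoskeleton and keratin genes, mitochondrial transcripts and ribosome biogenesis were called each time. The G1/S E2F targets were not called without vehicle replicate 1, and their median turned to -0.22 in G1 and -0.21 in Geminin-negative cells. The median of cytoskeleton and keratin genes shrank to -0.04 and -0.08 in these subsets. Leaving out vehicle replicate 1, 2 or 3 gave 6, 2 and 2 genes, of which 4, 2 and 2 were among the 11. No replicate block gave 1, and edgeR called 86.

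At 24 h of NCS, wild-type cells had less ANLN, a scaffold of the cytokinetic ring, which went from 2.65 (SD 0.566, n = 3) to 0.289, a log2 change of -2.51 ± 0.37 (SE; limma adjusted p = 0.0355). It was the only gene of 11060 to pass limma's test, with 640 genes at unadjusted p under 0.05. edgeR did not call it and called FBXO32 instead, which was higher. Nor was ANLN called with a pseudocount of 1, no detection filter, averages of the deposited log values, no replicate block or the run date as block. The mitotic kinase gene CDK1 (-2.63 ± 0.47), the condensin SMC4 (-2.10 ± 0.37), the topoisomerase TOP2A (-2.88 ± 0.53) and the ribonucleotide reductase subunit RRM2 (-2.40 ± 0.44) missed at an adjusted p of 0.0614. The p53 target TP53INP1 had 1.20 ± 0.35, the splicing regulator ZMAT3 0.98 ± 0.31 and C12orf5 (TIGAR) 1.03 ± 0.30, and none of these passed limma's test. As groups, G1/S E2F targets (median -1.07, 0 lower over all genes and 46 of 70 adjusted over the list alone), S phase markers (-1.15, 0 and 31 of 42), G2/M markers (-1.27, 1 and 44 of 63), homologous recombination genes (-0.61, 0 and 8 of 33) and end joining genes (-0.32, 0 and 2 of 19) were lower by camera. The p53 targets (median 0.27, 0 of 71 in both counts) and cytosolic ribosomal proteins (0.26, 0 of 72) were higher. None of these 7 lists passed with an estimated correlation (adjusted p = 0.25 to 0.285) or fry. Without the plate factor, the p53 targets passed both (adjusted p = 0.0333 and 0.0469). Against the wild-type cells of vehicle replicate 1 alone, of the same GEO sample, medians were -0.92 for G1/S targets, -1.33 for G2/M markers and 0.38 for p53 targets. In G1 cells only they were -0.67, -0.58 and 0.42. The list tests used both genotypes of vehicle replicate 1, so none of these medians is what the tests measured. Without vehicle replicate 1 or 2, 5 and 8 genes passed.

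In knockout cells at 24 h, 27 genes passed limma's test, all higher, led by the RNAs UGDH-AS1 (3.81 ± 0.51), KCNQ1OT1 (3.72 ± 0.49) and ESRG (3.39 ± 0.31), the gene ASTN2 (3.22 ± 0.34) and XAF1 (2.93 ± 0.45; limma adjusted p 3.71e-05 to 0.00636). All 27 had their highest value in a single cell of 4985 counts, which held a median of 92.3% of the unit's sum. Without cells under 10000 counts 0 genes passed (limma, 256 genes at unadjusted p under 0.05), and edgeR called 0 (354 at unadjusted p under 0.05). G1/S E2F targets (median -0.43), S phase markers (-0.47), G2/M markers (-0.61), homologous recombination (-0.25), end joining (-0.31) and ribosome biogenesis genes (-0.35) were lower by camera, with 0 genes lower over all genes and 3 G2/M markers adjusted over the list alone. The p53 targets (0.36), senescence-associated secretion (0.14), TGF-beta and YAP targets (0.28) and the amino acid response (0.07) were higher, with 0 genes over all genes in these lists and 1 in the last adjusted over the list alone. Against the knockout cells of vehicle replicate 1 alone, medians were -0.81, -0.82, -1.17 and -0.47 for the first 4 lists and 0.28 for p53 targets. The list tests used both genotypes of that replicate, so neither these medians nor those against all vehicle plates are what the tests measured. In G1 cells only, the medians of those lists were -0.16, -0.20, -0.14, -0.04 and 0.26. These rest on 4 cells at 24 h against vehicle units of 2 and 5 cells. None of these 10 lists passed with an estimated correlation (adjusted p = 0.328 to 0.642) or fry. The DNA damage inducible gene DDIT4 had 1.82 ± 0.38 (limma adjusted p = 0.0593). Without vehicle replicate 1, 5 lists passed and the G1/S, S phase and G2/M lists were not among them. Without the plate factor, 8 lists passed, and homologous recombination, end joining, senescence-associated secretion and the amino acid response were not among them. The p53 targets then also passed with an estimated correlation (adjusted p = 0.0245) and fry (adjusted p = 0.0313). Without vehicle replicate 1 or 3, 11 genes passed each time.

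In wild-type cells at 48 h, RRM2 went from 4.82 (SD 1.39, n = 3) to 0.391 (-2.95 ± 0.46), the tubulin regulator STMN1 from 9.26 (SD 1.02, n = 3) to 1.28 (-2.63 ± 0.30) and the proliferation marker MKI67 from 3.91 (SD 1.41, n = 3) to 0.253 (-2.98 ± 0.52). HIST1H4C (-3.11 ± 0.54), MCM7 (-2.61 ± 0.37) and KIAA0101 (-2.66 ± 0.37), a PCNA-binding factor, also fell. IGFBP5 (3.06 ± 0.46), PAPPA (2.68 ± 0.48), which cleaves IGF-binding proteins, smooth muscle actin ACTA2 (2.62 ± 0.37), CLSTN2 (2.63 ± 0.38), the actin-binding gene TAGLN (1.74 ± 0.34) and CDK6 (1.66 ± 0.36) rose. In all 91 genes passed limma's test, 28 higher and 63 lower (limma adjusted p of those named 0.00127 to 0.0389). After median-of-ratios scaling 132 passed, 90 higher and 42 lower, with the median log2 change of all genes at -0.109 before and -0.0044 after it. G1/S E2F targets (median -1.05, 8 of 70 lower over all genes, 41 adjusted over the list alone), S phase markers (-1.05, 4 and 30 of 42), G2/M markers (-1.45, 13 and 44 of 63), homologous recombination (-0.59, 0 and 6 of 33) and end joining (-0.40, 0 and 1 of 19) were lower by camera. TGF-beta and YAP targets (0.45, 2 of 25 higher over all genes, 4 higher and 1 lower adjusted over the list alone), G1 and CDK inhibitor genes (0.21, 1 higher over all genes, 3 higher and 1 lower adjusted over the list alone), senescence-associated secretion (0.25, 2 higher, then 3 higher and 2 lower), p53 targets (0.10, 0 in both counts), ribosomal proteins (0.26, 0 and 4) and mitochondrial transcripts (0.43, 0 and 3) were higher. None of the 11 passed with an estimated correlation (adjusted p = 0.125 to 0.212), and end joining alone passed fry (adjusted p = 0.0411). All 48 h cells came from a single plate, so plate and treatment cannot be told apart beyond the spread of the vehicle plates. All vehicle cells were harvested 24 h after DMSO, so the 48 h cells lack a vehicle of the same time. Time and NCS cannot be told apart there, nor in knockout cells at 48 h or in that part of the averages. With vehicle replicate 1 alone as control, the median of mitochondrial transcripts was 0.13 and that of senescence-associated secretion 0.02. Without vehicle replicate 3, 37 genes passed, and in G1 or Geminin-negative cells 0 did (limma, 286 and 456 genes at unadjusted p under 0.05). In both, 91 of the 91 genes kept their direction, and the median was -1.17 and -1.16 for G1/S targets and -0.75 and -1.10 for G2/M markers. The kept direction is in part fixed in advance, since both subsets hold 13 of the 14 cells at 48 h on which the genes were called.

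In knockout cells at 48 h, STMN1 went from 9.14 (SD 2.16, n = 3) to 0.714 (-3.26 ± 0.30), the histone variant gene H2AFZ from 10 (SD 2.73, n = 3) to 0.988 (-3.01 ± 0.30), RRM2 from 4.74 (SD 2.92, n = 3) to 0.152 (-3.48 ± 0.46) and MCM7 from 3.16 (SD 1.35, n = 3) to 0.175 (-2.93 ± 0.37). TAGLN (1.85 ± 0.34) and the basement membrane collagen COL4A1 (1.71 ± 0.34) rose, and the chaperonin HSPD1 (-1.46 ± 0.31) and the AP-1 subunit FOSL1 (-1.42 ± 0.31) fell. In all 89 genes passed limma's test, 15 higher and 74 lower, against 35 higher and 54 lower after median-of-ratios scaling. The p53 targets (median 0.35, 0 of 71 in both counts) were higher by camera (adjusted p = 7.63e-09), and adjusted p = 0.0288 with an estimated correlation, the only list of 13 to pass camera both ways. G1/S E2F targets (-1.23, 15 and 43 of 70 lower), S phase markers (-1.24, 10 and 28 of 42), G2/M markers (-1.46, 19 and 43 of 63), homologous recombination (-0.36, 0 and 2 of 33) and end joining (-0.45, 0 and 3 of 19) were lower by camera, over all genes and adjusted over the list alone. So were immediate early genes (-0.22, 2 and 3 of 23) and ribosome biogenesis (-0.49, 0 and 3 of 25). TGF-beta and YAP targets (0.58, 2 and 10 of 25 higher), G1 and CDK inhibitor genes (0.40, 0 and 2), apoptosis genes (0.06, 0 and 1), ribosomal proteins (0.16, 0 in both) and mitochondrial transcripts (0.32, 0 in both) were higher. These 12 lists had adjusted p = 0.11 to 0.296 with an estimated correlation, and the p53 targets and end joining passed fry (adjusted p = 0.0128 each). Medians against vehicle replicate 1 alone were 0.05 for mitochondrial transcripts and 0 for immediate early genes, whose fall thus rests on vehicle replicates 2 and 3. Without vehicle replicate 1, 39 genes passed, and in Geminin-negative cells 5 did. In the latter 89 of the 89 genes kept their direction, and the median was -0.55 for G1/S targets and -0.82 for G2/M markers. In G1 cells (7 at 48 h, vehicle units of 2 and 5) these medians were -0.40 and -0.59, and 89 of the 89 kept their direction.

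With both NCS times averaged, wild-type cells showed lower CDK1 (-2.62 ± 0.37), TOP2A (-2.72 ± 0.43), RRM2 (-2.67 ± 0.35) and the repair genes BRCA1 (-1.61 ± 0.33) and BRIP1 (-1.39 ± 0.27). TP53INP1 (1.26 ± 0.28), ZMAT3 (1.10 ± 0.25) and C12orf5 (1.01 ± 0.24) rose, as did ACTA2 (1.75 ± 0.28; limma adjusted p of all these 0.00132 to 0.0483). Of 11060 genes, 150 passed, 23 higher and 127 lower, and after median-of-ratios scaling 125 passed, 48 higher and 77 lower. Lower by camera were G1/S E2F targets (median -1.10, 24 of 70 over all genes, 58 adjusted over the list alone), S phase markers (-1.13, 15 and 37 of 42), G2/M markers (-1.34, 26 and 57 of 63), homologous recombination (-0.60, 3 and 17 of 33) and end joining (-0.48, 1 and 3 of 19). The p53 targets were higher (0.21, 3 of 71 over all genes, 4 adjusted over the list alone), with adjusted p = 0.0457 with an estimated correlation. The other 10 lists that passed camera, among them G1 and CDK inhibitor genes (0.23), interferon-stimulated genes (0.11), TGF-beta and YAP targets (0.09), ribosomal proteins (0.25) and mitochondrial transcripts (0.33), did not pass with an estimated correlation (adjusted p = 0.17 to 0.442). The p53 targets and end joining also passed fry (adjusted p = 0.0193 each). The median of mitochondrial transcripts turned to -0.05 against vehicle replicate 1 alone, and that of interferon-stimulated genes was -1.3e-05. Without vehicle replicate 2 or 3, 65 and 45 genes passed, and in G1 cells 0 did (limma, 393 genes at unadjusted p under 0.05, edgeR 404 in all cells). In G1 cells 150 of the 150 genes kept their direction, and the median was -0.86 for G1/S targets and 0.36 for p53 targets.

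**Figure D3:**
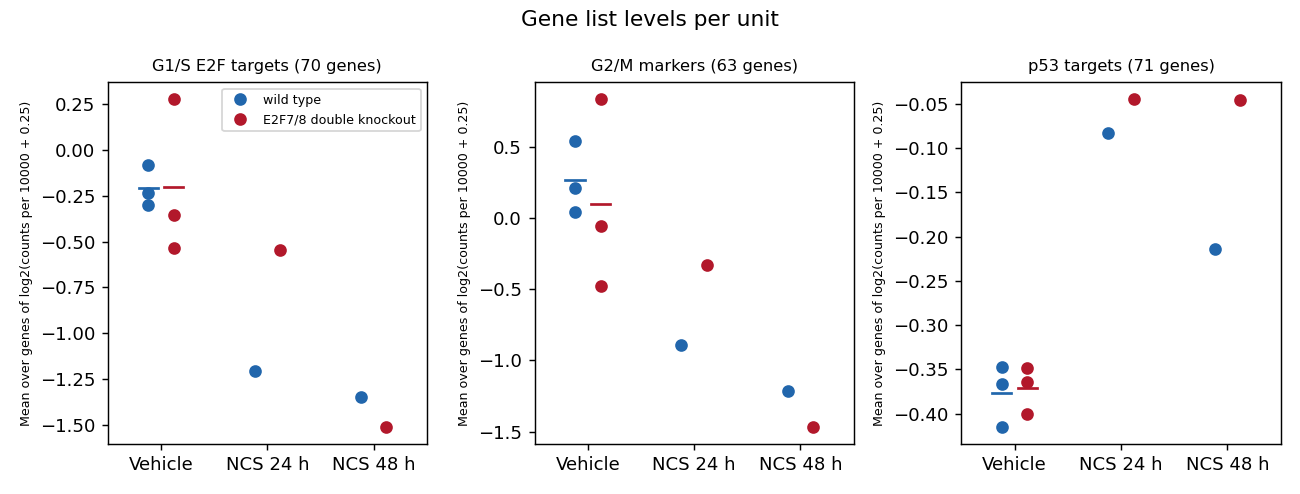
Points give the mean over list genes of log2(counts per 10000 + 0.25) (vertical axes, which differ between panels) for each unit by treatment (horizontal axis), and bars give vehicle means of 3 units. Lists of 70 G1/S E2F targets and 63 G2/M markers lie lower in all 4 NCS units than the vehicle mean of their genotype, and 71 p53 targets lie higher.

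In knockout cells, averaged over both times, MCM7 (-1.86 ± 0.28), MCM5 (-1.93 ± 0.32), UHRF1 (-1.90 ± 0.34) and ASPM (-1.95 ± 0.37) fell, and the matrix genes FN1 (1.10 ± 0.22), COL4A1 (1.17 ± 0.26) and IGFBP7 (1.14 ± 0.25) rose (limma adjusted p 0.00431 to 0.04). In all 100 genes passed, 36 higher and 64 lower, against 56 higher and 43 lower after median-of-ratios scaling, 9 higher and 46 lower in cells with at least 10000 counts, 9 and 39 without each gene's highest cell, and 16 and 101 by edgeR. For 25 of the 36 higher genes, ASTN2, KCNQ1OT1 and UGDH-AS1 among them, the cell of 4985 counts held more of the 24 h unit's sum than all its other cells together, and 4 of the 36 also passed in cells with at least 10000 counts. The p53 targets were higher (0.34, 0 of 71 over all genes, 4 adjusted over the list alone), with adjusted p = 0.0155 with an estimated correlation, while TP53INP1 (1.12 ± 0.28), RPS27L (0.85 ± 0.23) and the CDK inhibitor CDKN1A (1.16 ± 0.43) missed. G1/S E2F targets (-0.76, 10 and 34 of 70 lower), S phase markers (-0.81, 6 and 23 of 42), G2/M markers (-1.0, 16 and 42 of 63), homologous recombination (-0.32, 0 in both), end joining (-0.42, 0 and 2), immediate early genes (-0.20, 2 and 3) and ribosome biogenesis (-0.41, 1 and 3) were lower by camera, over all genes and adjusted over the list alone. TGF-beta and YAP targets (0.37, 3 and 9 of 25), G1 and CDK inhibitor genes (0.32, 0 and 1), senescence-associated secretion (0.05, 1 and 2), ribosomal proteins (0.07, 0 in both) and mitochondrial transcripts (0.25, 0 in both) were higher. These 12 lists had adjusted p = 0.154 to 0.619 with an estimated correlation, and the p53 targets and end joining passed fry (adjusted p = 0.0095 and 0.0166). The median of immediate early genes turned to 0.067 against vehicle replicate 1 alone. In G1 cells medians were -0.34 for G1/S targets, -0.36 for S phase markers, -0.30 for G2/M markers, -0.08 for homologous recombination and 0.28 for p53 targets. There 95 of the 100 genes kept their direction. These values rest on 4 cells at 24 h and 7 at 48 h, against vehicle units of 2 and 5 cells. Without vehicle replicate 1 or 3, 25 and 66 genes passed.

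Whether the genotype difference itself changed with NCS was tested on the differences within pairs. FN1 had a log2 change of 1.10 ± 0.22, BRIP1, a helicase of crosslink repair, 1.77 ± 0.38, CDK1 1.67 ± 0.41 and MTRNR2L1 1.01 ± 0.21, and none passed (limma adjusted p 0.305, 0.314, 0.742 and 0.305). Under alternatives FN1 passed with averages of the deposited log values, without vehicle replicate 3 and without each gene's highest cell (limma adjusted p 0.00333, 0.00405 and 0.0141). Of 11060 genes 0 passed, with 521 at unadjusted p under 0.05 against 553 expected by chance, and edgeR called 0. By camera, the differences of G1/S E2F targets (median 0.26), S phase markers (0.27), G2/M markers (0.35), homologous recombination (0.21) and TGF-beta and YAP targets (0.15) were higher with NCS, and those of immediate early genes (-0.28), ribosome biogenesis (-0.21) and ribosomal proteins (-0.19) lower (adjusted p 7.00e-07 to 0.0444). None of the 8 passed with an estimated correlation (adjusted p = 0.763 to 0.974), and ribosome biogenesis alone passed fry (adjusted p = 0.0165). Adjusted over the list alone, 1 G1/S, 1 S phase, 1 homologous recombination, 2 G2/M and 2 TGF-beta and YAP genes passed, and 0 of each over all genes. The mean G1/S difference was 0.58, -0.12 and -0.45 in the vehicle pairs, 0.66 at 24 h and -0.16 at 48 h, so the pairs of each treatment went both ways. The 2 pairs above 0 came from a single GEO sample and had dyed wild-type cells, and the 3 below 0 had dyed knockout cells. In each pair the sign was also opposite to that of the knockout minus wild-type Geminin-negative share. That share differed by -15.6, 14.2 and 64.6 percentage points in vehicle, -19.7 at 24 h and 0.89 at 48 h. The signs thus go with the dye, the sample and the phase mix rather than with NCS, and these cannot be told apart. The test took the 5 pairs as independent. Without vehicle replicate 3, 2 genes and 3 lists passed, and the G1/S, S phase, G2/M and homologous recombination lists were not among them. Lists of cholesterol synthesis, glycolysis and hypoxia, and retinal pigment epithelium identity passed in none of the 9 comparisons (smallest camera adjusted p 0.124, 0.153 and 0.529), but cholesterol synthesis did at 24 h in wild-type cells without vehicle replicate 1 or without the plate factor. Histone, tubulin, ribosomal and mitochondrial genes have near-identical copies, and antisense RNAs share loci with other genes, so reads may be split between them.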

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

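The tests on the 24 h knockout genes, on the DiD dye and on a CDT1 reporter dimmed by one factor, and the subsets of cells by phase or by counts, were chosen after the data were seen. LAMA4 differed by 0.45 (log2, knockout minus wild type) in vehicle replicate 1, against 0.84 to 0.95 in the other pairs. LTBP2 differed by -0.25 in vehicle replicate 1, against -0.83 to -1.02. The log10 median Geminin signal differed by -1.12 in vehicle replicate 3, against 0.0458 to 0.485. In each, a single pair stood far from the rest, and chance flags about 2.2 of 44 such groups, against 3 found. The genotype difference changed with NCS for 8 lists by camera with preset correlation, at adjusted p 0.00251 for G1/S E2F targets, 0.00674 for S phase markers, 0.00139 for G2/M markers, 0.00251 for homologous recombination genes, 0.00674 for immediate early genes, 0.0444 for TGF-beta and YAP targets, 0.0444 for ribosome biogenesis and 7.00e-07 for cytosolic ribosomal proteins (adjusted p = 0.763 to 0.974 with an estimated correlation). The 5 pairs were taken as independent, though vehicle replicate 1 and the 24 h cells are of one GEO sample.

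The 27 genes higher in knockout cells at 24 h had a median log2 change of 2.01, and 0.309 without each gene's highest cell, which argues against a rise shared by the 22 cells of the unit. Without cells under 10000 counts 0 of the genes were still called, so a shallow cell may set these calls. The cell of 4985 counts was highest for 27 of 27 genes. What made that cell differ was not tested.

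M/early G1 calls were in excess among knockout cells. A CDT1 reporter dimmed by one factor in all knockout cells would lower their highest signal as it lowers the median. Among Geminin-negative cells, wild-type signals were multiplied by the ratio of the medians, and knockout cells above all of them were counted. After NCS there were 11, 4 of 15 at 24 h (29 wild-type cells, probability by chance 0.0101) and 7 of 15 at 48 h (13 wild-type cells, 0.00543). This argues against one factor alone, with an unchanged mix of phases, as the whole account there. The cells counted were as many as the knockout G1 calls (4 and 7). A smaller factor beside a different phase mix thus stays open. All these probabilities take the cells of a single unit as independent and the ratio of medians as fixed. In vehicle replicates 2 and 3 there were 10, 5 of 16 and 5 of 11 (7 and 2 wild-type cells, 0.130 and 0.359), too few wild-type cells to decide. A reporter dimmed or absent in part of the knockout cells stays open. Its planned test, a lower CDT1 signal among knockout G1 calls, found that in 1 of 5 combinations and decides nothing, since every G1 call lay above every M/early G1 call in that signal. More cells fresh from mitosis could raise G2/M transcripts in M/early G1 over G1 knockout cells. That log2 difference was 1.004 in vehicle replicate 2 (11 and 5 cells), -0.0816 at 24 h (11 and 4) and 0.0353 at 48 h (8 and 7). A rise of the size in vehicle was thus not seen after NCS, but each value rests on few cells of a single unit. The mean was 0.319 (95% interval -1.16 to 1.80, 3 combinations), which leaves more cells fresh from mitosis open. Effects of the dye cannot be told apart either. Where knockout cells carried it, their share was 57.9% against 10%, 76.9% against 0% and 50.0% against 0% of wild-type cells. Where wild-type cells carried it, undyed knockout cells had 0% against 3.23% in vehicle replicate 1, which goes with the dye, and 50.0% (28.2 to 71.8) against 15.2% (5.11 to 31.9) at 24 h, which goes against it, with overlapping intervals. An effect of the deletion itself was not tested.

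MCM5, MCM6 and DUT, higher in knockout vehicle cells by a mean of 1.12, might reflect the mix of phases. In Geminin-negative cells the mean was 0.534, under the bound of 0.559 set in advance for such a mix (0.5 of the value in all cells). The change was -0.58 ± 0.49 (SE, 3 pairs) and 2 of the 6 units held 2 cells, so the bound was not passed by more than the SE, a demand added after the values were seen, and the mix is left undecided. An upward shift of the whole G1/S list is argued against, since its mean in these cells was -0.474, -0.179 and -0.547 in the 3 pairs. The list thus lay lower in knockout cells in each pair, and that lower level was not tested. Shallow cells are argued against by 1.01 in cells with at least 10000 counts. Loss of E2F7 and E2F8 stays open beside the phase mix.

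For the 22 genes between genotypes in vehicle, 1 of 10 splits of the 6 units, the real one, gave as many (highest other 1), and 10 splits are too few for a share under 0.05. For the 11 genes over all treatments, 7 of all possible splits of the 10 units, a share of 0.0556, gave as many (highest other 26), so chance was not excluded. The other 6 parted only the 24 h pair, which holds the cell of 4985 counts. Of 16 splits that parted all pairs, the other splits gave 0 at most.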

How the results depend on the processing

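Chosen after the data were seen were edgeR, the run date as block, 24 h lists without the plate factor, vehicle replicates 2 and 3 as 1 pair, vehicle replicate 1 alone as control at 48 h, cells with at least 10000 counts, leaving out each gene's highest cell, Geminin-negative or G1 cells only, and scaling for single NCS times. Of 2468 values of 164 named gene results under alternatives, 2459 kept their direction. This agreement is in part fixed in advance. The leading genes of each comparison were picked for the same sign in every pair or against every vehicle unit, and the alternatives reuse the same cells. Called genes that kept their direction in G1 or Geminin-negative cells also reuse cells on which they were called. Genes called are given in the order genotype in vehicle (22), genotype over all treatments (11), 24 h wild type (1), 24 h knockout (27), 48 h wild type (91), 48 h knockout (89), both times wild type (150), both times knockout (100) and change of the genotype difference (0; limma, 521 at unadjusted p under 0.05). The cause of the moves was not tested, except that subsets of cells hold fewer cells. For NCS against vehicle edgeR also had no plate block, so more than the method changed there. A pseudocount of 1 gave 11, 4, 0, 50, 37, 34, 49 and 41 for the first 8. No detection filter gave 10, 3, 0 and 56 for the first 4, and for 48 h knockout and both averages 38, 65 and 65. Averages of log values gave 34 for vehicle genotype, 0, 0, 50, 38 for the single NCS arms, 21 for averaged knockout and 2 for the change. Median-of-ratios scaling gave 9 in vehicle, 2 for 24 h wild type and 51 for 24 h knockout. Without the replicate block, which comes from the pairing in the design, there were 0, 1, 0 and 15 for the first 4, and 93 and 51 for the averages. It moved 48 h counts within 1.5 times (75 and 85). The run date as block gave 0 and 14 at 24 h, 75 and 75 at 48 h, and 93 and 49 for the averages. Vehicle replicates 2 and 3 as 1 pair gave 32 and 8 for genotype. edgeR gave 56 and 86 for genotype, 1 (FBXO32, higher, in place of ANLN) and 0 at 24 h, 279 and 234 at 48 h, and 404 and 117 for the averages. Cells with at least 10000 counts gave 68 and 21 for genotype, 6 and 0 at 24 h, and 251 and 55 for the averages. Without each gene's highest cell there were 42 in vehicle, 0 and 0 at 24 h, 48 for averaged knockout and 1 for the change. Geminin-negative cells gave 7, 3, 0, 0, 0, 5, 1 and 5, and G1 cells 0 in each of the first 8. Leaving out a vehicle replicate gave 7 to 30, 2 to 6, 1 to 8, 11 to 40, 37 to 102, 39 to 80, 45 to 108, 25 to 72 and 0 to 2 (treatment fits used the consensus correlation of all units). Lists called fell from 8, 7, 7, 10, 11, 13, 11, 13 and 8 to 0, 0, 0, 0, 0, 1, 1, 1 and 0 with an estimated correlation, and to 0, 1, 0, 0, 1, 2, 2, 2 and 1 with fry. Without the plate factor 9 and 8 were called at 24 h, and 1 in each genotype, the p53 targets, with an estimated correlation and with fry. Without a vehicle replicate they ranged from 5 to 9 for vehicle genotype, 5 to 10 for 24 h knockout and 3 to 7 for the change. Against vehicle replicate 1 alone at 48 h, the medians of TGF-beta and YAP targets in knockout cells and of senescence-associated secretion in wild-type cells were 0.97 and 0.02, against 0.58 and 0.25, those of mitochondrial transcripts 0.13 in wild-type and 0.05 in knockout cells, against 0.43 and 0.32, and that of immediate early genes in knockout cells 0, against -0.22. E2F7 in vehicle was -1.01, passed at -0.41 with averages of log values, and ranged from -1.47 to -0.72 without a replicate.

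Reversed gene values in G1 cells were -0.043 for MCM5 and -0.10 for MT-ND2 in vehicle, 0.32 for PLAU in vehicle (1.10 in Geminin-negative cells), -0.32 for XAF1 and -0.087 for TP53INP1 at 24 h in knockout cells, and 0.050 for FOSL1 in knockout cells over both times. With at least 10000 counts, ESRG was at -0.23 and XAF1 at -0.038. The knockout minus wild-type Geminin-negative share ranged from -5.05 to 15 percentage points without a replicate, and the log10 Geminin signal from -0.14 to 0.26. Re-weighting to equal phase shares was not run, since only G1 occurs in every unit. At least 8 cells per unit and no requirement on builds left 22 and 11 genes. Units hold 10 to 33 cells, and the simulation recovered 5% of 4-fold changes at 24 h in wild-type cells, so a low count of calls there excludes little. At 48 h in wild-type cells it recovered 2%, but with far fewer calls than the real data gave. Its spread was chosen, so that share need not hold for them.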

Other observations

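The shares here were compared after the result was seen. Among Geminin-positive cells, 13 of 37 wild-type and 18 of 23 knockout cells carried the mid S/G2 call, which has low CDT1 signal (median 50 units, against 1601 in early S calls). The share was 60.0% in knockout against 61.9% in wild-type cells in vehicle replicate 1 and 100%, 50.0%, 100% and 100% against 0% in vehicle replicates 2 and 3, at 24 h and at 48 h, with 1 to 10 knockout cells each and a single cell of each genotype at 48 h. The wild-type shares of 0% rest on 3, 8, 4 and 1 cells, so with up to 3 cells allowed they exclude little. These cells are part of the mid S/G2 shares of the phase calls above.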
